A study of Mus musculus with 16 samples.

How the data were processed

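Peak lists of 9 ChIP-seq libraries were analysed, each called on its own library by the authors and with coordinates in mm9. Per the submitters' processing notes, CASAVA 1.8.1, Trimmomatic 0.22, SAMtools 0.1.18 and MACS were used. The aligner is not given in the sources used here. Per the file headers, the replicate 1 factor peaks were called with MACS against IgG at a p cutoff of 1e-05 and an enrichment factor of 8, with reads of 50 bp and fragments of 200 bp. Per the file headers, replicate 1 histone peaks were called with MACS 1.4.2 against input at a p cutoff of 1e-05, and all replicate 2 peaks with MACS 2.1.1.20160309 against input at a q cutoff of 0.05. Replicate number therefore goes together with the caller and the control for TEAD4, and with the caller version and the tag length for the marks (99 and 101 bp in replicate 1, 51 bp in replicate 2). A difference between replicates cannot be assigned to any of these.

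The deposited replicate 1 files give the count of reads or tags in each peak. The deposited fold enrichment is a ratio of ChIP reads to those expected from the control. The deposited score is −10log10(p), and the replicate 2 files hold deposited −log10 values of the p-value and the q-value. Per the file headers the false discovery rate is a p-value type fraction in the factor files and a percent in the replicate 1 histone files. The deposited pileup is the signal at the summit of replicate 2 peaks. These values are the authors' and were used to describe, rank or filter peaks within a list.

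Samples were grouped by the cell type, antibody and replicate number in the labels. Nothing in the labels says that replicates came from separate cultures, so their spread may be technical. Peaks on the mitochondrial genome and on random or unplaced sequence were left out of the comparisons, which removed 2 ES TEAD4 peaks, 84 TEAD4 replicate 2 peaks and between 36 and 97 peaks of each histone list. The replicated TEAD4 set was the replicate 1 peaks sharing at least 1 bp with a replicate 2 peak. A replicated mark was the sequence covered in both replicates, 39.7 Mb for H3K27ac and 76.2 Mb for H3K4me1.

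Overlaps were compared with 1000 random placements (seed 7) of the first set on its own chromosomes with lengths kept, between the first and last position seen in any list. These placements ignore mappability and gaps. The p values are one-sided for a higher overlap. Wilson intervals have a confidence level of 95% and cover counting error only, and peaks are not biological replicates. Fold enrichments were compared with 100000 permutations. The local input level was derived from the deposited replicate 2 pileup and fold as (pileup + 1) / fold − 1.

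Gene names came from the authors' annotation in the replicate 1 factor files, which assigns a peak to a gene when it lies inside it or up to 5 kb upstream. Of the 2787 symbols at TS TEAD4 peaks, 2582 matched the GRCm38.p6 gene table, 2262 of them protein-coding, and that table was used only for names and gene order. The gene tests had been planned with a window of 50 kb around each TSS, which needs an mm9 annotation, so the authors' assignment was used instead. It favours long genes, and histone marks were not tested by gene. Fisher's exact tests compared each of 10 lists with the other protein-coding genes for 4 factor sets, with Benjamini-Hochberg adjustment over the 40 tests. Odds ratios had 0.5 added to each count. Lists were fixed before the data were examined: trophoblast stem cell, differentiated trophoblast, pluripotency, Hippo pathway, YAP-TEAD target, fibroblast, other-lineage, KLF and SP family, FGF and MAPK pathway and housekeeping genes.

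Genes were named by a fixed rule: Tead4 and Med13l, up to 6 members of each list with the highest TEAD4 fold, members without a peak, the 10 strongest TEAD4 peaks, the strongest peaks of the other factor sets and the 10 genes with the most TEAD4 peaks. Members without a peak are named only for the 3 lists that passed the test, and the strongest KLF5 and ES peaks only in part. Genes at shared sites, Yap1, Nf2 and Wwc1 were chosen after their values were seen. The replicated H3K27ac intervals were ranked by width in place of the planned sum per gene. A motif test at TEAD4 summits was not run, since it needs a genome sequence.

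The overlap and gene list steps were tested on simulated data. Simulated peaks had the lengths of replicate 1 TEAD4 peaks, also in the runs of 280 and 133 peaks. Unplanted peaks were placed as in the comparison itself. The runs therefore check the calculation, and not its fit to the shorter KLF5 and ES peaks. With 50% of 5987 random peaks planted in H3K27ac, 51.7% were found where 51.4% was due. For 280 peaks with 5% planted, 6.43% were found where 7.64% was due (permutation p = 0.002), and for 133 peaks with none planted, 1.50% where 2.75% was due (permutation p = 0.872). Of simulated lists of 20 genes, 99.5% were detected at a peak rate of 60%, and 3% at a rate of 15%, the background set in the simulation. The background in the data was lower, 10.2% of protein-coding genes. Detection used unadjusted p values, and simulated genes did not differ in length. These runs therefore cover neither the effect of gene length nor the adjusted threshold. Alternatives covered the peak threshold, the overlap needed, each replicate alone, list length, direction, random placement within H3K4me1, chromosome 11, peak centres and gene length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.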

Results

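Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the transcription factors TEAD4 and KLF5 and the histone marks H3K4me1 and H3K27ac in mouse stem cell lines of the C57BL/6 strain. Trophoblast stem (TS) cells are derived from the trophoblast lineage that forms the placenta, and embryonic stem (ES) cells from the inner cell mass. Both were grown on feeder cells, and the cells collected for the assay were feeder-free per the labels. H3K4me1 marks enhancers, and H3K27ac marks active enhancers and promoters. The series title places the work in the control of Tead4, which encodes a factor required for the trophoblast lineage of the blastocyst. There were 16 libraries, 12 from TS cells and 4 from ES cells, of which 7 were IgG or input controls. Peak lists were analysed for the other 9 libraries, 7 from TS cells and 2 from ES cells. TEAD4, H3K4me1 and H3K27ac had 2 libraries each in TS cells. KLF5 in TS cells and both factors in ES cells had 1 library each, so those results have no replicate check.

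The lists differed widely in length and depth. TEAD4 in TS cells gave 6086 peaks in replicate 1 and 32425 in replicate 2. H3K27ac gave 29179 and 53436 peaks, and H3K4me1 gave 91768 and 120541. KLF5 gave 280 peaks in TS cells and 112 in ES cells, and TEAD4 gave 135 in ES cells. The headers gave 26331492 tags for TEAD4 replicate 2, 87267413 and 25539893 for H3K27ac, and 116652867 and 25598243 for H3K4me1. The total depth of the replicate 1 factor libraries is unknown. Every replicate 1 TEAD4 peak in TS cells had a false discovery rate of at most 0.019. The lowest rate among TS KLF5 peaks was 0.190, and 1 of the 112 ES KLF5 peaks had a rate of at most 0.05. Of the 135 ES TEAD4 peaks 3 did, 2 on the mitochondrial genome and 1 on chromosome 1 from 24618368 to 24622225. The sets therefore differ in reliability, and the TS KLF5 and ES lists carry the weakest evidence.

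TEAD4 binding in TS cells recurred at the same places in both replicates. Of the 6086 replicate 1 peaks, 5987 (98.4%, 95% Wilson interval 98.0 to 98.7) overlapped a replicate 2 peak, against 1.70% for random placement (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). The share was 70.2% with both lists held to 6086 peaks, and 74.55% where 50% of the interval had to be covered. Recovery was 93.7% among the 1247 peaks of lowest fold enrichment and 100% among the 1194 of highest. The fold enrichments of the libraries were correlated across the 5987 shared peaks (Spearman's rho 0.701), which are not independent replicates. In the other direction, 6268 replicate 2 peaks (19.4%) met a replicate 1 peak. Replicate 2 peaks found in both had a median fold of 14.9, and the 26073 found in replicate 2 alone had one of 5.67. For H3K27ac, 24232 of 29143 replicate 1 peaks (83.2%) met a replicate 2 peak, against 5.30% at random, and for H3K4me1 58959 of 91671 (64.3%) did, against 10.2% (permutation p = 0.001 for both). Where 50% of the interval had to be covered, the H3K27ac share was 51.8%. The H3K4me1 share fell to 33.0% for peaks with a −10log10(p) of at least 100, against 5.27% at random. It fell to 13.7% where 50% of the interval had to be covered, against 2.38% at random. These shares were 6.269 and 5.75 times random, and the share without these limits was 6.297 times random. The median H3K4me1 peak was 1832 bp long in replicate 1 and 445 bp in replicate 2. Of the 120448 H3K4me1 peaks of replicate 2, 95.78% met a replicate 1 peak, against 12.24% at random. The 5987 shared TEAD4 peaks were used below as the replicated set.

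TEAD4 in TS cells lay mostly in marked chromatin. H3K27ac present in both replicates overlapped 4071 of the 5987 peaks (68.0%, 95% Wilson interval 66.8 to 69.2), 23.9 times the random share of 2.85%. H3K4me1 overlapped 4909 (82.0%, 81.0 to 83.0), 12.6 times the random share of 6.50%. Both marks were present at 3567 peaks (59.6%), H3K4me1 alone at 1342 (22.4%), H3K27ac alone at 504 (8.42%) and neither at 574 (9.59%). Both permutation p values were 0.001, the smallest possible. Placed at random only within replicated H3K4me1, 43.8% of peaks met H3K27ac, so that the TEAD4 share was 1.55 times this background (permutation p = 0.001). The random peaks were all centred in H3K4me1, while the observed share also counts TEAD4 peaks outside it, so the sets are not alike. Of the 4909 TEAD4 peaks in H3K4me1, 3567 met H3K27ac. The shares depended on how an overlap was counted: with each peak reduced to its centre base, 41.3% lay in H3K27ac and 30.8% in H3K4me1. With replicate 2 peaks alone, 43.4% lay in H3K27ac and 52.3% in H3K4me1.

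**Figure D1:**
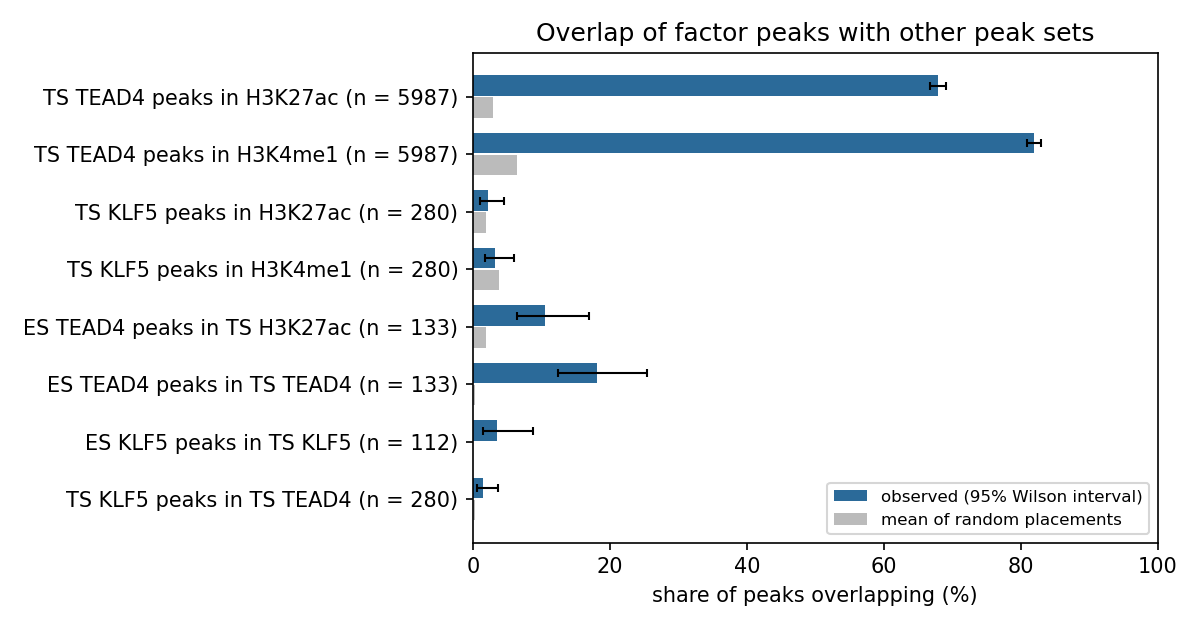
Share of peaks (x axis, %) of each factor set that overlapped another set by at least 1 bp. Blue bars are observed shares with 95% Wilson intervals, grey bars the mean of 1000 random placements, and n is the number of peaks. TEAD4 in TS cells reached 68.0% and 82.0% in the marks, and KLF5 in TS cells had 2.14% and 3.21%. The sets are not alike: KLF5 peaks came from 1 library and none had a false discovery rate below 0.190. Their median length was 146 bp, against 884 bp for TEAD4 replicate 1.

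Of the replicated TEAD4 peaks, 1200 (20.04%) lay within 5 kb of an annotated transcription start site (TSS), 1944 (32.5%) lay inside a gene farther away, and 2843 (47.5%) had no gene in the authors' annotation. H3K27ac was present at 78.2% (75.7 to 80.4), 66.6% (64.5 to 68.7) and 64.7% (62.9 to 66.4) of these. H3K4me1 was instead lowest near a TSS, at 74.4% (71.9 to 76.8), 85.9% (84.3 to 87.4) and 82.5% (81.1 to 83.9). TEAD4 peaks inside H3K27ac had a median fold enrichment of 8.82 and those outside 7.71, a log2 difference of 0.19 (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give). With replicate 2 peaks alone the log2 difference was 0.37 (medians 7.43 and 5.73). In turn, 3888 of the 24232 recurrent H3K27ac peaks (16.0%) carried a replicated TEAD4 peak, and 12144 (50.1%) carried a peak of TEAD4 replicate 2.

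The strongest TEAD4 peak of TS cells lay in an intron of Rtn1, a reticulon gene, on chromosome 12 from 73444110 to 73445299 (mm9), with a fold enrichment of 63.9 in replicate 1 and 85.1 in replicate 2. Peaks in Tada2a (48.5-fold, chromosome 11) and in an intron of Gng7, a G protein subunit gene (45.9-fold), followed. Fgfr2, which encodes a receptor through which FGF4 maintains TS cells, held an intronic peak on chromosome 7 from 137379872 to 137380992 with 38.6-fold enrichment. A 3' UTR peak in Hsd17b7 (37.5-fold) was in neither replicated mark. The remaining 5 of the 10 strongest peaks were assigned to Gm12508 (40.4-fold), to Zfp520-ps (38.6-fold) or to no gene (40.8-, 39.3- and 37.5-fold). By number of peaks, Tead1 and Etl4 led with 9 each, followed by Ptpn14 and Usp29 with 7. Rbm20, Mob3b, Meis1, Prkn, Dlgap1 and Ahnak each had 6. Peaks anywhere inside a gene were counted, which favours long genes, and this ranking was not adjusted for length.

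Genes of the Hippo pathway, the kinase cascade that controls the TEAD coactivator YAP, carried TEAD4 peaks in TS cells more often than other genes. A replicated peak was assigned to 12 of the 21 Hippo genes (57.1%), against 10.2% of other protein-coding genes (Fisher's exact test, two-sided, odds ratio 11.6, adjusted p = 3.06e-06 over 40 tests). Against genes of the same length class the odds ratio was 5.52 (permutation test, adjusted p = 0.00267). Amotl2, which encodes an angiomotin that binds YAP, had a peak over its 5' UTR with 37.1-fold enrichment, and the kinase gene Lats2 had one at its TSS with 31.2-fold. Ptpn14 reached 27.9-fold, Tead1 25.4-fold, Vgll4, a TEAD cofactor, 23.9-fold, and Ajuba 17.6-fold. Yap1 itself had a peak at its TSS of 9.92-fold. Lats1, Tead2, Tead3, Stk3, Sav1, Mob1a, Mob1b, Amot and Frmd6 had no assigned peak. Since 2843 replicated peaks had no gene and peaks found in replicate 2 alone were not assigned, this does not show absent binding. Nf2 and Wwc1 also carried peaks and lie on chromosome 11, whose input level was raised.

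Targets of YAP and TEAD also passed the test, with peaks at 9 of 18 genes (50%, odds ratio 8.82, adjusted p = 0.000246 by the same exact test). Ptpn14 is in both lists. Arhgef17 reached 14.0-fold and Ccn2, a matricellular protein gene, 15.4-fold at its TSS. Asap1 (10.7-fold), Nt5e (9.92-fold) and Nuak2 (9.55-fold) followed. Of the 9 genes with a peak, 6 had one in H3K27ac. Ankrd1, Axl, Fjx1, F3, Tgfb2, Igfbp3, Birc5, Foxf2 and Gadd45a had no assigned peak. Trophoblast stem cell genes had peaks at 10 of 20 (50%, odds ratio 8.82, adjusted p = 0.000114 by the exact test), all 10 with a peak in H3K27ac. Fgfr2 and Tead4 had the strongest, and that of Fgfr2 lay outside H3K27ac, with 1 of its 4 peaks inside. Gata3, a trophoblast transcription factor gene, had an intronic peak of 14.0-fold, Elf5, another, had 5 peaks of up to 10.7-fold, Esrrb had 9.18-fold and Bmp4 7.35-fold. Cdx2, Eomes, Tfap2c, Id2, Sox21, Sox2, Zic3, Klf5, Krt8 and Satb1 had no assigned peak. With peaks limited to 5 kb from the TSS, this list had an adjusted p of 0.0637, odds ratio 5.80.

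The other lists did not pass the test. FGF and MAPK pathway genes had peaks at 6 of 21 (exact test, adjusted p = 0.127), led by Etv5 at 14.3-fold, with Map2k1, Spred2, Etv4, Fgfr4 and Spry4 between 7.71- and 5.51-fold. That list passed with peaks within 5 kb of the TSS (exact test, adjusted p = 0.0205, odds ratio 7.09). Spred2 and Etv4 lie on chromosome 11. Without that chromosome, and with no 5 kb limit, the list had 4 of 18 (exact test, adjusted p = 0.504). Pluripotency genes and KLF and SP family genes each had 5 of 20 (exact test, adjusted p = 0.233). These included Dppa4 (17.3-fold), Nanog (14.7-fold, upstream), Zfp42 (12.1-fold), Tfcp2l1 (10.3-fold) and Sall4 (7.71-fold), and Sp4 (23.1-fold), Sp1 (10.7-fold), Klf7 (10.3-fold), Sp2 (9.07-fold, chromosome 11) and Klf3 (6.25-fold). Within 5 kb of the TSS, the pluripotency list and the KLF and SP list each had 4 of 20 (exact test, adjusted p = 0.0637, odds ratio 5.80). The trophoblast stem cell list had the same result there, so that setting did not set it apart from them. Differentiated trophoblast genes had 2 of 19, Hand1 (5.30-fold) and Gcm1 (8.08-fold), and fibroblast genes, which would mark feeder cells, had 2 of 20, Mmp3 (7.35-fold) and Fbn1 (5.51-fold), each with an adjusted p of 1. Genes of other lineages and housekeeping genes had 0 of 20 each.

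**Figure D2:**
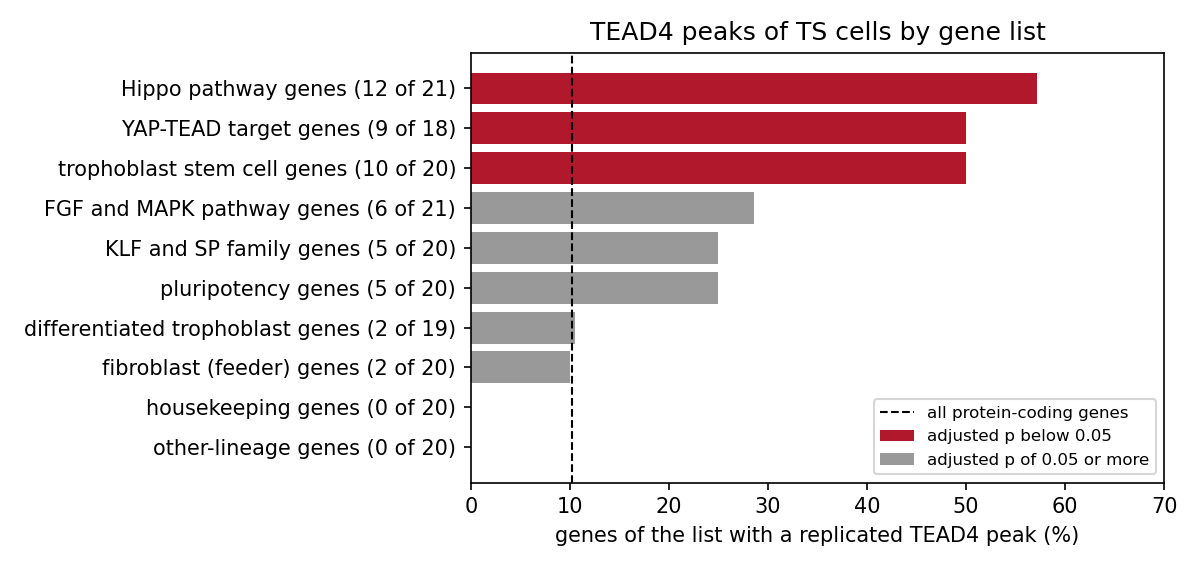
Percent of the genes of each list with a replicated TEAD4 peak in TS cells (x axis), with counts beside each name. The dashed line is the share of all protein-coding genes, 10.2%, and red bars passed the test. The Hippo pathway list reached 57.1%.

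The Tead4 gene itself was bound in TS cells. Its TSS, inferred from the authors' distances, lies at 128250832 on chromosome 6. A replicate 1 peak from 128249983 to 128251050, over the 5' UTR and an intron, had 29.0-fold enrichment, and the replicate 2 peaks around the gene reached 53.2-fold. Weaker replicate 1 peaks of 11.02- and 9.55-fold lay inside the gene. Within 50 kb of the TSS there were 3 TEAD4 peaks in replicate 1 and 6 in replicate 2, with 9 and 14 H3K27ac peaks and 8 and 20 H3K4me1 peaks. No ES or KLF5 peak lay there. Med13l, a Mediator subunit gene on chromosome 5 chosen before the data were examined, had no TEAD4 peak assigned to it. The 2.98 Mb between the annotated peaks at Fbxo21 and Rph3a, which holds Med13l by gene order in GRCm38.p6, contained 6 replicated TEAD4 peaks. The strongest lay from 121344259 to 121345328 (11.02-fold), near the annotated Rph3a peak that starts at 121401928, and 5 of the 6 were in H3K27ac. The interval holds 30 coding genes, and chromosome 5 as a whole had 2.16 replicated TEAD4 peaks per Mb. The count was therefore not raised there, and none of these peaks is tied to Med13l. These data do not measure contacts between chromosomes.

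**Figure D3:**
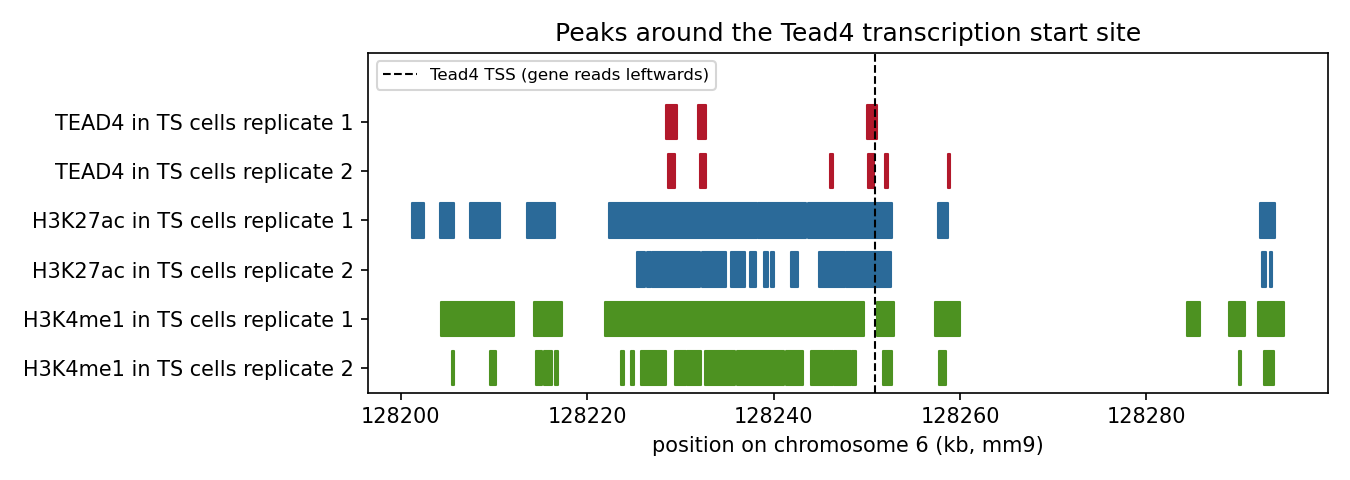
Peaks within 50 kb of the Tead4 TSS on chromosome 6 (x axis, kb, mm9), one line per TS cell library. The dashed line marks the inferred TSS at 128250832, with the gene to its left, and the replicate 1 TEAD4 peak over it had 29.0-fold enrichment.

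TEAD4 peaks of ES cells fell partly on the strongest TEAD4 sites of TS cells. Of the 133 ES peaks outside the mitochondrial genome, 24 (18.05%, 95% Wilson interval 12.4 to 25.5) met a replicated TS peak, against 0.252% at random (permutation p = 0.001). Among peaks with a −10log10(p) of at least 100, 7 of 14 ES peaks (50%) did. Only 1 of the 133 ES peaks had a false discovery rate of at most 0.05, so that score did not mark reliable ES peaks. The 24 TS peaks had a median fold of 21.7, against 8.45 for the others, a log2 difference of 1.36 (permutation p = 1e-05, two-sided). Genes at the shared sites were Gng7, Igf2bp1, Ajuba, Lats2, Cdk5rap1, Agrn, Tead1 and Amotl2. Igf2bp1 lies on chromosome 11. In ES cells, 4 of the 21 Hippo genes had a TEAD4 peak, Tead1, Lats2, Amotl2 and Ajuba (exact test, odds ratio 163, adjusted p = 1.81e-06). Each of those ES peaks had a false discovery rate of 1, and the 5 peaks with the highest ES fold, up to 19.1 on chromosome X, were not at TS sites. H3K27ac of TS cells covered 14 of the 133 ES peaks (10.5%, random 1.91%, permutation p = 0.001), and 5 of the 14 strict ones (35.7%). Most of the covered ES peaks lay at the sites shared with TS TEAD4, where 58.3% of the 24 TS peaks were in H3K27ac. Against random placement within H3K4me1 regions the ES share was lower, 10.5% against 33.2%. The random peaks were all centred in H3K4me1 and the ES peaks were not, so this says nothing about H3K27ac within H3K4me1.

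KLF5 gave few sites in either cell type. Of the 112 ES peaks, 4 (3.57%, 1.397 to 8.83) met a TS KLF5 peak, against 0.00536% at random (permutation p = 0.001). These included the promoters of Ctnna1, the alpha-catenin gene, and Myst3, a histone acetyltransferase gene. The Ctnna1 peak, on chromosome 18 from 35278163 to 35278705, had 25.5-fold enrichment and 113 reads, and was the only ES KLF5 peak with a false discovery rate of at most 0.05. In TS cells, 6 of 280 KLF5 peaks (2.14%) lay in H3K27ac, against 1.89% at random (permutation p = 0.444), and 9 (3.21%) in H3K4me1, against 3.85% (permutation p = 0.763). With H3K27ac replicate 1 alone the H3K27ac share was 4.64%, against 3.35% at random (permutation p = 0.147). With H3K4me1 replicate 2 alone the H3K4me1 share was 7.86%, against 3.99% at random (permutation p = 0.004). With H3K4me1 replicate 1 alone it was 10.0%, against 10.2% at random (permutation p = 0.564). No TS KLF5 peak had a false discovery rate below 0.190, so shares near random do not show that KLF5 avoids marked chromatin. The strongest TS KLF5 peak was at Gm18326 with 52.6-fold enrichment and a false discovery rate of 1. KLF5 peaks met replicated TEAD4 peaks at 4 of 280 places in TS cells (1.43%, random 0.268%, permutation p = 0.003), of which a pair lay at Nemf. None of the 29 KLF5 peaks with a −10log10(p) of at least 100 met a TEAD4 peak of that strength. With all peaks of TEAD4 replicate 2 in place of the replicated set, 19 of the 280 (6.79%) met one, against 0.702% at random. In ES cells 3 of 112 KLF5 peaks met a TEAD4 peak (2.68%, permutation p = 0.001), none of them at an annotated gene. Their false discovery rates were 0.511 to 0.547 in the KLF5 list and higher in the TEAD4 list. Libraries of different antibodies in the same cells can share artefact regions, so these sites do not show joint binding.

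Chromosome 11 carried the most TEAD4 peaks per Mb in TS cells. It held 610 of the 5987 replicated peaks (10.2%), or 5.13 per Mb, against a median of 2.32 and a maximum of 3.23 on the other autosomes. H3K27ac was raised there 1.73- and 1.82-fold over the autosomal median, H3K4me1 1.43- and 1.83-fold and TS KLF5 1.92-fold. The ES lists had ratios of 1.08 for TEAD4 and 1.21 for KLF5, from 6 peaks each. The local input level under TEAD4 replicate 2 peaks was 3.98 reads on chromosome 11 and between 2.70 and 2.99 on the other autosomes. Chromosome X held 0.526 replicated TEAD4 peaks per Mb. With chromosome 11 left out, the TEAD4 share in H3K27ac was 67.3% and the number of gene lists passing stayed at 3.

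**Figure D4:**
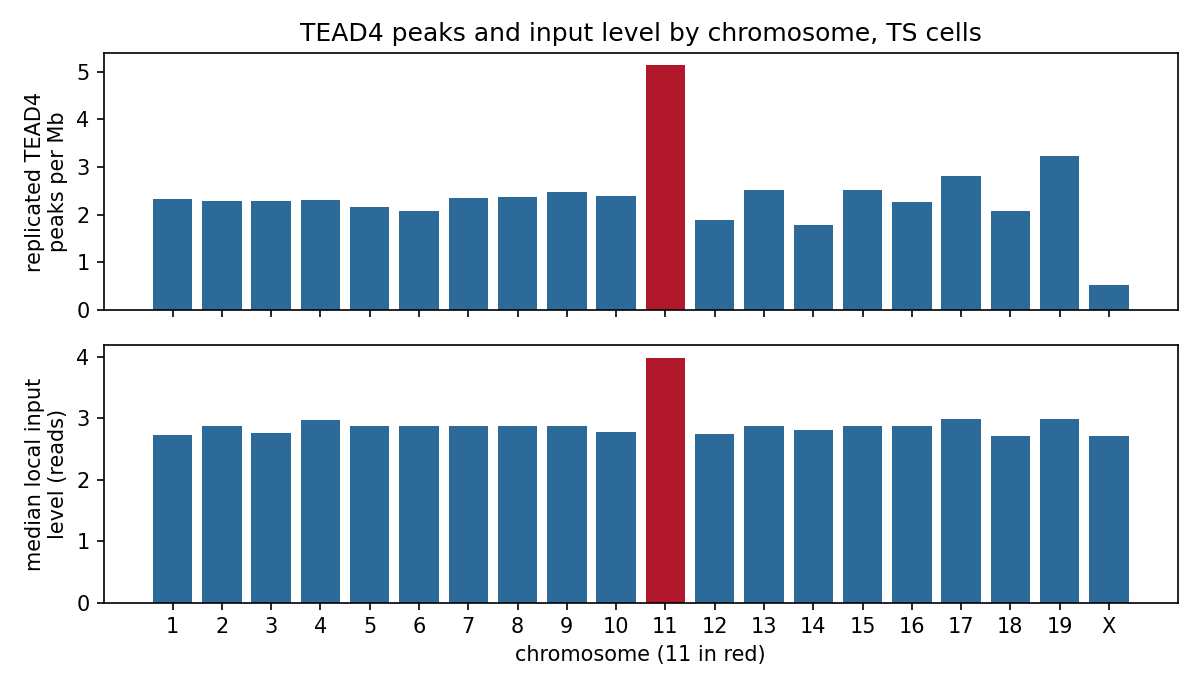
Replicated TEAD4 peaks per Mb (upper y axis) and median local input level in reads under TEAD4 replicate 2 peaks (lower y axis) for each chromosome of TS cells (x axis). Chromosome 11, in red, stands at 5.13 peaks per Mb and an input level of 3.98 reads.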

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

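The tests of peak threshold, of weak ES enrichment and of mitochondrial reads were chosen after the results were seen, as were the tests between cell types.

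The share of TEAD4 peaks in H3K27ac of TS cells differed between the ES library and the TS set, 10.5% of 133 ES peaks against 68.0% of 5987 TS peaks (Fisher's exact test, adjusted p = 6.91e-42 over 4 tests). Among peaks with a −10log10(p) of at least 100 the shares were 35.7% of 14 and 72.8% of 2808. The mark was measured in TS cells for both, and the called peaks had a median length of 156 bp in ES cells and 884 bp in TS replicate 1, where a longer peak meets a mark more easily. The share of KLF5 peaks in TS H3K27ac also differed between the libraries, 8.04% of 112 ES peaks against 2.14% of 280 TS peaks (exact test, adjusted p = 0.0306), with the ES peaks at Ctnna1, Myst3, Gata2, Wdfy1, Fndc3b, Kcnk13 and Clcn4-2 among them. The other tests did not pass: KLF5 in TS H3K4me1 had 8.04% of ES and 3.21% of TS peaks (exact test, adjusted p = 0.0775), and KLF5 at TEAD4 peaks of the same cells 2.68% and 1.43% (exact test, adjusted p = 0.413). Peaks are not replicates and each ES and KLF5 set came from 1 library, so these tests compare libraries and not cell types. In the ES TEAD4 list, 2 peaks on the mitochondrial genome held 3201 of the 7110 reads in peaks (45.0%), and no other list had a mitochondrial peak.

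The ES lists were short, with 135 TEAD4 and 112 KLF5 peaks. Weak enrichment in the ES libraries may contribute, since outside the mitochondrial genome at most 0.893% of the peaks of either list had a false discovery rate of at most 0.05 (2.22% of all ES TEAD4 peaks). Reads from the mitochondrial genome and its nuclear copies stay open for ES TEAD4: mitochondrial peaks and peaks of 1 kb or longer held 65.6% of the reads in peaks, but this restates what was seen, the share of the whole library is unknown, and no table shows that the long peaks are copies. Mitochondrial reads in the ES KLF5 library stay open too: its list had 0 mitochondrial peaks, but peaks were called against IgG and do not limit the reads. Less binding in ES cells stays open and was not tested.

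TEAD4 replicate 2 gave 5.31 times as many peaks as replicate 1. A looser threshold is argued against, since 32011 replicate 2 peaks passed the p cutoff of replicate 1, although the callers compute p differently. Off-target background stays open: 82.1% of the 26073 peaks found in replicate 2 alone lay in replicate 1 H3K27ac or H3K4me1, 7.21 times the random share of 11.4%, but the control was input, and background that gathers in open chromatin would give a high share too. Depth, control and caller also stay open, since the depth of replicate 1 is unknown. No biological explanation was tested.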

How the results depend on the processing

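The chromosome 11, peak centre, gene length and 5 kb settings were chosen after the data were seen. Of 114 alternatives over 24 results, 102 kept direction and side of the threshold. Of the 114, 64 concerned main results, of which 58 were kept. The others were odds ratios of single gene lists, most of which did not pass in any setting. Within 5 kb of the TSS 3 lists passed, but not the same ones. Trophoblast stem cell genes fell out (exact test, adjusted p = 0.0637), and FGF and MAPK genes came in (exact test, adjusted p = 0.0205). Among peaks with a −10log10(p) of at least 100, KLF5 met TEAD4 at 0% in both cell types (of 29 TS and 2 ES peaks). Of those 29 TS KLF5 peaks, 1 (3.45%) lay in H3K4me1, against 2.08% at random (permutation p = 0.4725). Placed within H3K4me1, random peaks met H3K27ac more often than TS KLF5 (2.14%) and ES TEAD4 (10.5%) did. That background is itself rich in H3K27ac. Its random peaks were all centred in H3K4me1, where only 3.21% of TS KLF5 peaks lay, so the lower shares do not compare H3K27ac within H3K4me1. TS KLF5 in H3K4me1 was 7.86% with mark replicate 2 alone, above 3.99% at random, and 10.0% with replicate 1 alone, near 10.2% at random. The odds ratio of fibroblast genes turned below 1 at 0.460 (strict peaks), 0.516 (within 5 kb) and 0.980 (gene length), and that of differentiated trophoblast genes at 0.852 without chromosome 11, none past the threshold. Apart from these constructions, the cause was not tested. Against genes of similar length, 3.73 Hippo genes were due and 12 found (permutation test, adjusted p = 0.00267), and 3 lists passed as before. No paired analysis was possible because the results are overlaps of peak lists and no model is fitted across replicates. TEAD4 peaks met the mark of the same replicate number at 69.1% and 49.9% for H3K27ac and at 92.5% and 53.4% for H3K4me1. Across numbers, replicate 1 and 2 TEAD4 peaks met H3K27ac at 76.5% and 49.8% and H3K4me1 at 82.6% and 78.5%. Motif tests, windows of 10 and 100 kb, an H3K27ac background and gene lists from replicate 2 alone were not run for want of a genome or gene names. No interval was called in all 4 factor sets, so none could be left out. With unknown depth and few peaks, a missing ES or KLF5 peak does not show absent binding. A gene without an assigned TEAD4 peak in TS cells does not show it either, since many peaks had no gene.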

Other observations

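The tests on chromosome 11 were planned before their results were seen.

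The widest intervals of replicated H3K27ac in TS cells carried TEAD4. Each of the 10 widest held at least 1 replicated peak. The widest, 15062 bp on chromosome 6 from 31025891 to 31040952, had no assigned gene and held 3 peaks of up to 9.18-fold. Others lay at Lasp1, Hic2 and Inpp1, and one at Gm19705 and Gm16880 held 4 peaks of up to 26.8-fold. Wide intervals have more room for a peak, and this was not tested. H3K27ac peaks with TEAD4 had a median length of 3066 bp in replicate 1, and those without 2094 bp.

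Chromosome X had few TEAD4, H3K27ac and H3K4me1 peaks in TS cells. The TEAD4 density was 0.225 and 0.309 times the autosomal median in the replicates, H3K27ac 0.237 and 0.357 times, and H3K4me1 0.171 and 0.106 times. Local input lay above the floor of its measure at 17.9% of TEAD4 replicate 2 peaks on X, against a median of 51.8% on autosomes other than 11. For H3K4me1 the values were 6.01% and 35.0%, and for H3K27ac 13.4% and 50.1%. Fewer sites on X therefore cannot be told apart from a lower input level there. TS KLF5, at 0.0550 peaks per Mb, lay within the autosomal range of 0.0498 to 0.202. The ES ratios were 1.18 for TEAD4 and 1.17 for KLF5, from 9 and 8 peaks. In each ES list only 1 analysed peak had a false discovery rate of at most 0.05, so these ratios give no contrast of cell types.

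Chromosome 11 held the most TEAD4 peaks per Mb, and extra copies of chromosome 11 in the cultured line, not measured directly, may contribute, since the median input level was 1.39 times that of the other autosomes, and 1.33 and 1.46 times under H3K4me1 and H3K27ac peaks. These ratios are against a level near the floor of the measure: a median of 51.8% of TEAD4 replicate 2 peaks on the other autosomes lay above it, and 95.7% on chromosome 11. More enhancer chromatin cannot be told apart from this. TEAD4 gave 74.1 peaks per Mb of replicated H3K4me1 there, within the range of 65.6 to 106 on other autosomes, but calls of H3K4me1 would rise with copies too. Gene density on chromosome 11, 13.5 coding genes per Mb, was matched on chromosome 7 with 13.6, where TEAD4 had 2.34 peaks per Mb; per coding gene, chromosome 11 had 0.379 TEAD4 peaks and the other autosomes 0.172 to 0.375.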
